A study of Homo sapiens with 6 samples.

How the data were processed

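Expression was measured in K562, an established human erythroleukaemia cell line, on 6 single-colour arrays hybridised with biotin-labelled cDNA made from total RNA. The sample titles name 2 groups of 3 replicates, cells with a control vector and cells with a vector for the microRNA miR-543, and these titles gave every group. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical.

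The values used are log2 signals per probe set as the authors deposited them, given to 2 decimals. Per the submitters' processing notes the tools were Transcriptome Analysis Console 4.0 and RMA, a method that corrects the background, normalizes between arrays and summarises probes. The RMA variant, the annotation release and any genome build were not given in the sources used here. No detection calls were used, so a low signal was not sorted into present or absent. The table held 21448 probe sets, each a transcript cluster on all 6 arrays, and 0 columns of other samples. Medians lay between 5.99 and 6.01 and upper quartiles between 9.61 and 9.66 on the 6 arrays. The number of arrays limits the precision.

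Gene names came from the platform annotation through the gene identifier, and current symbols and chromosomes from the RefSeq gene table of the GRCh38.p14 assembly, which was used for names and gene order and not for coordinates. A single symbol was given for 17709 probe sets (17687 distinct symbols), several for 0, and 3739 probe sets were unnamed here. All 17709 identifiers matched, and 17709 symbols were unchanged. The chromosome of the gene table was the same as that in the probe set identifier for 99.94% of named probe sets. Values identical to those of another probe set on all 6 arrays were found for 82 probe sets, 0 of them among the calls.

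The groups were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes without a trend on all 21448 probe sets, with no block, filter or weights. Changes are miR-543 vector minus control vector on the log2 scale, folds are taken from them, and SE is the moderated standard error of the log2 change. Every limma p was two-sided, and adjusted p-values are by the Benjamini-Hochberg method over all probe sets unless a list is named. A probe set was called at an adjusted p under 0.05, and calls with at least a 2-fold change (log2 change of 1) were also counted. The prior had 6.26 degrees of freedom and an SD of 0.201, beside a median residual SD of 0.199. TET1, TET2 and TET3 were also tested by two-sided exact permutation tests, whose smallest possible p is 0.1 with 3 arrays against 3, so these tests cannot fall under 0.05. Intervals are 95% intervals.

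Gene groups were tested with camera at its preset correlation of 0.01, adjusted over 28 lists. Camera with an estimated correlation and the directional test of fry were run beside it. The latter asks whether the members move on balance in 1 direction and does not compare a list with other genes. Its mixed test, for change in either direction, was added after the data had been seen. The 28 lists held 659 distinct genes, 578 of them measured, and were compiled from general knowledge. They cover reported miR-543 targets, DNA demethylation, DNA methylation, myeloid chromatin regulators, microRNA machinery, the DLK1 to MEG3 locus, JAK-STAT signalling, TGF-beta and fibrosis, erythroid, megakaryocyte, myelomonocytic, lymphoid, stem and progenitor, stromal and fibroblast and epithelial or kidney line markers, cholesterol synthesis, oxidative phosphorylation, hypoxia and glycolysis, cell cycle genes of G1/S and of G2/M, replication histones, ribosome biogenesis and MYC, ER stress and heat shock, the ATF4 stress response, immediate early genes, NF-kB and inflammation, the interferon response, and apoptosis. Genes were named by rule. TET1, TET2, TET3 and any probe set of MIR543 were always named. So were the 12 largest rises and 12 largest falls in log2 among calls with a single gene symbol whose miR-543 arrays all lay on the same side of all control arrays. Up to 4 members of each list with the smallest unadjusted p were also named. Small RNAs, unnamed loci and probe sets with several symbols were counted and not named among the largest rises and falls. The groups, tests, lists, naming rule and alternative settings were fixed before the data were examined. The 13 cancer-testis gene families of the additional observations were defined by symbol after the calls had been seen, and the patterns for SSX and CTAG were narrowed after a first run because they also took in unrelated symbols.

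The steps were tested on simulated data of the same size, 21448 probe sets in 3 arrays against 3 with 50 changed probe sets at each size. At log2 changes of 0.5, 1, 1.5 and 2 the simulated comparison recovered 4%, 64%, 88% and 96% of them. Of 134 simulated calls, 8 (5.97%) were false. A simulated shift of 0.5 in every measured member of the erythroid list passed camera, with 0 other lists past the threshold. The simulated noise was independent between probe sets, so this run does not show how camera performs on correlated members or smaller shifts.

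The alternatives were a replicate block, eBayes with trend and robust settings, a further quantile normalization, arrays shifted to the same median, filters at the 30th and 50th percentiles of mean signal, array weights, 1 probe set per symbol, an unadjusted p under 0.05 with a 2-fold change, limma treat against a log2 change of 0.5, and each array left out in turn. A planned search for miR-543 seed matches in 3 prime UTRs was left out, because transcript sequences were not used here. miR-543 itself was not analysed here, since no probe set carried its name.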

Results

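The data describe mRNA levels in K562 cells, an erythroleukaemia line that carries the BCR-ABL1 fusion, on 3 arrays of cells with a control vector and 3 arrays of cells with a miR-543 vector. Array medians lay between 5.99 and 6.01 on the log2 scale. Across probe sets, which are not independent replicates, Pearson's r was 0.9945 to 0.9957 for the 6 pairs of arrays within a group and 0.9931 to 0.9951 for the 9 pairs between groups. The first principal component held 31.6% of the variance and placed the control arrays between -23.8 and -8.43 and the miR-543 arrays between 10.3 and 22.7. The second held 20.8%.

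The series title names TET1 and TET2, enzymes that oxidise 5-methylcytosine in DNA, as targets of miR-543, and the first comparison asks whether their mRNAs differed between the vectors. TET1 (TC1000007861.hg.1, chromosome 10) averaged 9.20 ± 0.075 with the control vector and 8.70 ± 0.18 with the miR-543 vector (SD, n = 3). The log2 change was -0.50 (SE 0.15, 95% interval -0.83 to -0.18), or 70.5% of the control level, and all 3 miR-543 arrays lay below all 3 control arrays. TET2 (TC0400008318.hg.1, chromosome 4) averaged 8.24 ± 0.15 and 8.16 ± 0.16 (SD, n = 3), a log2 change of -0.08 with a 95% interval of -0.42 to 0.25. TET3 (TC0200008065.hg.1, chromosome 2), the remaining enzyme of the family, averaged 8.01 ± 0.065 and 8.09 ± 0.13 (SD, n = 3), a log2 change of 0.08 with a 95% interval of -0.23 to 0.39. TET1 did not pass over all probe sets (adjusted p = 0.247) and passed when adjusted over the list alone, the 3 TET genes (adjusted p = 0.0178), a list prompted by the study's own title and so not independent evidence of a direction. Its exact permutation p was 0.1, the smallest that 3 arrays against 3 can give. For TET2 and TET3 the adjusted p was 0.901 and 0.896 over all probe sets, 0.592 and 0.592 over the list alone, and the exact permutation p was 0.6 and 0.5. The change of TET1 minus that of TET2 was -0.42 (exact permutation p = 0.3), and minus that of TET3 it was -0.58 (exact permutation p = 0.1), and with 0.1 as the smallest possible p these tests could not show a difference between the enzymes. In simulated data 4% of probe sets with a log2 change of 0.5 were called. Protein was not measured, and no probe set carried the name of miR-543. These mRNA values therefore cannot decide whether TET1 or TET2 is a target.

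**Figure D1:**
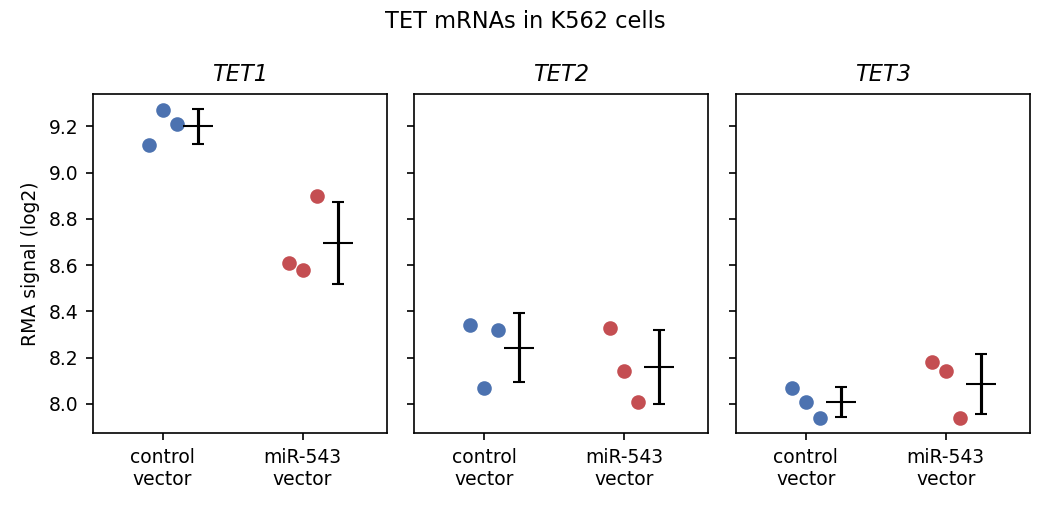
RMA signal (log2) of TET1, TET2 and TET3 on each array of K562 cells with the control vector or the miR-543 vector, with points for the 3 arrays of a group and bars for the mean and SD. The TET1 arrays lie at 9.12 to 9.27 with the control vector and at 8.58 to 8.90 with the miR-543 vector, while the arrays of TET2 and of TET3 overlap between groups.

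The second comparison covered all probe sets and asked which mRNAs differed between the vectors. SLCO4C1, a transporter of organic anions, fell by 3.44 on the log2 scale (SE 0.22), from 11.0 ± 0.32 to 7.61 ± 0.37 (SD, n = 3), a 10.8-fold difference with an adjusted p of 3.24e-04. AGMO, which cleaves ether lipids, fell 4.46-fold from 8.92 ± 0.21 to 6.76 ± 0.20 (SD, n = 3). The transcription factor TBX15 fell 4.27-fold from 10.1 ± 0.086 to 8.05 ± 0.25 (SD, n = 3), and both genes had an adjusted p of 7.13e-04. ST8SIA4, a sialyltransferase that makes polysialic acid, fell 4.25-fold (adjusted p = 0.00166). SPRR2D, a small proline-rich protein of the cornified envelope, fell 4.02-fold (adjusted p = 0.00414), with the caution that probes may read its close paralogs. With the miR-543 vector ST8SIA4 and SPRR2D averaged 5.15 ± 0.26 and 5.18 ± 0.50 (SD, n = 3), below the array medians of 5.99 to 6.01.

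Of the other named falls, CDH18, a cadherin, fell by 1.79 (SE 0.18, adjusted p = 0.00316), and IL1RAP, a co-receptor for interleukins of the IL-1 family, fell by 1.73 (SE 0.21, adjusted p = 0.00605). IL1RAP went from 5.38 ± 0.38 to 3.65 ± 0.25 (SD, n = 3), the latter below the array lower quartiles of 3.98 to 4.03. The size of its fall is therefore uncertain. POPDC3, a membrane protein that binds cAMP, fell by 1.72 (adjusted p = 0.00336). FGF13, an intracellular fibroblast growth factor homolog, fell by 1.71 from 11.8 ± 0.23 to 10 ± 0.15 (SD, n = 3; adjusted p = 0.00202). ZC2HC1A and SLC27A6, the latter a fatty acid transport protein, each fell by 1.59 (adjusted p = 0.00664 and 0.00257). CATSPERB, a subunit of the sperm calcium channel, fell by 1.58 (SE 0.14, adjusted p = 0.00152).

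The rises were smaller in fold. CYTIP, which binds cytohesins in blood cells, rose 2.64-fold from 5.49 ± 0.076 to 6.89 ± 0.17 (SD, n = 3; log2 change 1.40, SE 0.15, adjusted p = 0.00323). FAT1, an atypical cadherin, rose 2.41-fold (adjusted p = 0.00998), and STX11, a syntaxin of granule release in lymphocytes, rose 2.33-fold (adjusted p = 0.0122). STX11 went from 4.46 ± 0.12 to 5.69 ± 0.29 (SD, n = 3), both below the array medians of 5.99 to 6.01, so the size of its rise is uncertain. FCGR1A, a high-affinity receptor for IgG with near-identical gene copies that probes may share, rose 2.28-fold from 9.46 ± 0.19 to 10.6 ± 0.16 (SD, n = 3; adjusted p = 0.00908). GSDME, a pore-forming gasdermin, rose 2.24-fold (adjusted p = 0.0117). CLTCL1, a clathrin heavy chain, rose 2.10-fold (adjusted p = 0.00908), and FGD4, an exchange factor for CDC42, rose 2.05-fold (adjusted p = 0.0237). PPP1R3C, which directs protein phosphatase 1 to glycogen, and CLEC2B, a C-type lectin, each rose by 1.00 on the log2 scale (adjusted p = 0.0171 and 0.0111). The amino acid transporter SLC7A8 rose 1.99-fold (adjusted p = 0.0142). TMEM54 and the thromboxane synthase TBXAS1 rose 2.12-fold and 2.09-fold and lay nearest the threshold (adjusted p = 0.0488 and 0.0498), and each lost its call when the arrays were rescaled, TMEM54 after a further quantile normalization (0.0544) and TBXAS1 after a shift to equal medians (0.0511). Of the 12 named rises 11, 6 and 8 lost the call without control replicates 1, 2 and 3, and 8, 5 and 4 without miR-543 replicates 1, 2 and 3, with adjusted p-values of the lost calls between 0.0515 and 0.205.

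Of the 21448 probe sets, 122 were called, 28 as rises and 94 as falls, and 76 of these changed at least 2-fold, 12 up and 64 down. A single gene symbol was given for 111 calls, 24 rises and 87 falls. All 122 had the 3 arrays of 1 group above the 3 of the other, as had 3301 of all probe sets (15.4%, where chance gives 10%). At an unadjusted p under 0.05 there were 2276 probe sets, where 1072 would be expected by chance. The count was 34 without control replicate 1, 56 without control replicate 2, 48 without control replicate 3, and 50, 55 and 59 without miR-543 replicates 1, 2 and 3, and it was 252 with the trend and robust settings and 12 when tested against a log2 change of 0.5. Over 14 alternative fits run for single genes (13 for IL1RAP and STX11, which the 50th-percentile filter removed) the 12 named falls and CYTIP stayed called and the other 11 named rises each lost the call at least once. Tested against a log2 change of 0.5, 10 of the 12 named falls passed, IL1RAP and ZC2HC1A did not (adjusted p = 0.0739 and 0.0938), and 0 of the 12 named rises passed (CYTIP, 0.0691).

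**Figure D2:**
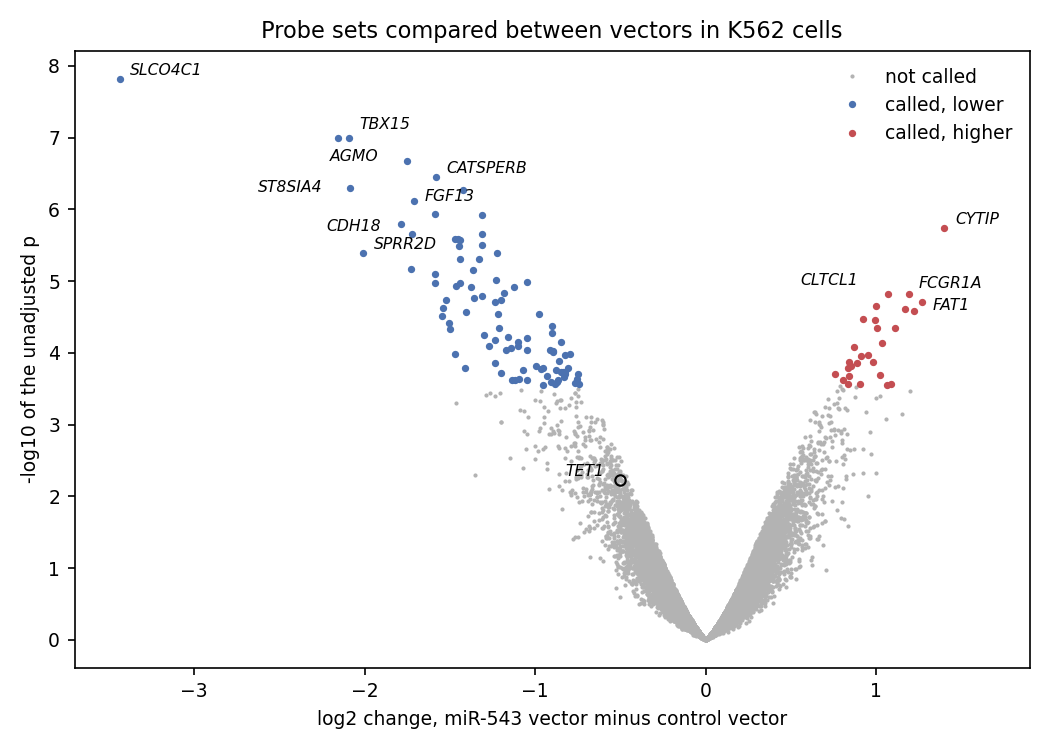
Log2 change (miR-543 vector minus control vector) on the horizontal axis against -log10 of the unadjusted limma p on the vertical axis for each of 21448 probe sets, coloured where the adjusted p was under 0.05. The 94 falls reach further from 0 (SLCO4C1, -3.44) than the 28 rises (CYTIP, 1.40), and TET1, circled, lies at -0.50 among the probe sets that were not called.

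**Figure D3:**
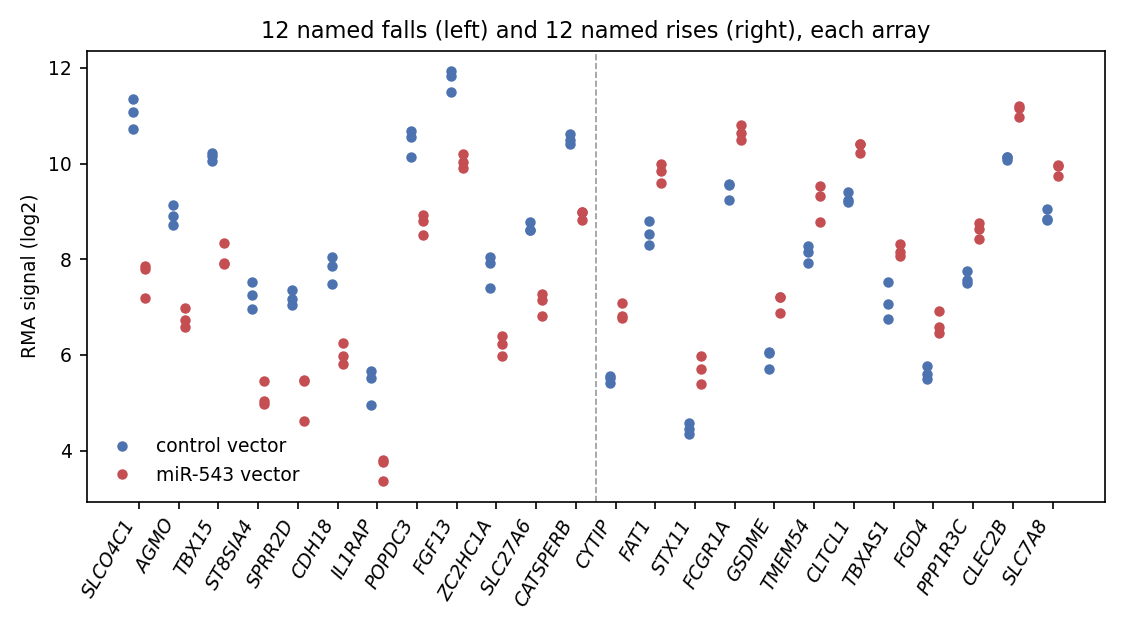
RMA signal (log2) on each array for the 12 named falls at the left and the 12 named rises at the right, with blue points for the control vector and red points for the miR-543 vector, 3 arrays each. The 3 arrays of each group lie apart for all 24 genes, as the naming rule requires, and SLCO4C1 has the largest distance between group means, 11.0 against 7.61.

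The gene lists asked whether whole programmes moved, beginning with genes reported as miR-543 targets. TWIST1, a transcription factor of mesenchymal cells, fell by 1.54 (SE 0.21) from 7.40 ± 0.31 to 5.86 ± 0.36 (SD, n = 3; adjusted p = 0.0114). The call of TWIST1 was lost without control replicate 2 (adjusted p = 0.0506) or control replicate 3 (0.0643), within a range of 0.00119 to 0.0643 over its alternatives. TWIST1 was the only called member of the 17 measured targets, over all probe sets and adjusted over the list alone. The deacetylase SIRT1 had a log2 change of -0.40 and PAQR3 one of 0.36 (adjusted p = 0.403 and 0.466). Of the 17 targets 12 lay at or below 0 (DKK1 was unchanged), with a median of -0.09. The list did not pass (camera adjusted p = 0.279, and 0.8 with an estimated correlation). Also on it were TET1 (adjusted p = 0.0505 over the list alone) and TET2, the targets named in the series title. The list is therefore not independent of the first comparison.

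Genes of TGF-beta signalling, fibrosis and stroma held the other called members. SPARC, a secreted protein that binds collagen, fell 2.83-fold (SE 0.22 on the log2 scale) from 7.64 ± 0.091 to 6.14 ± 0.50 (SD, n = 3; adjusted p = 0.0174). TGFBR2, the type II receptor for TGF-beta, fell by 1.23 (SE 0.21) from 6.63 ± 0.20 to 5.39 ± 0.42 (SD, n = 3; adjusted p = 0.035). Adjusted over the list alone, 4 of the 23 measured stromal and fibroblast genes passed, all lower: SPARC (0.00108), COL6A1 (log2 change -0.71, 0.0225), COL5A1 (-0.60, 0.0284) and COL5A2 (-0.53, 0.0461). These collagens lay low, at control means of 4.42, 5.19 and 4.71, below the array medians of 5.99 to 6.01. Signal over background was not tested. The stromal list had 16 members above 0, a median of 0.15 and a mean of -0.04, so the signs differed, and did not pass (camera adjusted p = 0.955). Of 23 TGF-beta and fibrosis genes TGFBR2 alone passed over all probe sets and over the list alone (0.00319), TGFB3 had a log2 change of 0.55 and SKIL one of -0.48, and the list had a camera adjusted p of 0.728. The call of SPARC was lost without control replicates 1, 2 or 3 (adjusted p = 0.0997, 0.067 and 0.0932) or miR-543 replicate 1 (0.0768), over a range of 0.00172 to 0.0997. The call of TGFBR2 was lost without control replicates 1, 2 or 3 (0.166, 0.14 and 0.0822) or miR-543 replicates 1 or 3 (0.0881 and 0.109), over a range of 0.00989 to 0.166.

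The lists of DNA demethylation, DNA methylation, myeloid chromatin regulators, microRNA machinery and the DLK1 locus held no called member. Among 17 measured genes of DNA demethylation 9 lay below 0 (median -0.02), with log2 changes of -0.63 for CXXC5, which binds unmethylated CpG, and 0.39 for the isocitrate dehydrogenase IDH2. Within that list TET1 and CXXC5 had an adjusted p of 0.0505 over the list alone, and the camera adjusted p was 0.565. Of 12 DNA methylation genes 8 lay above 0 and 4 below, with a median of 0.03 and a camera test that pointed downward (adjusted p = 0.955), and the maintenance methyltransferase DNMT1 had a log2 change of -0.25. Of 19 myeloid chromatin regulators 14 lay below 0 (median -0.13, camera adjusted p = 0.325). The Polycomb protein SUZ12 had a log2 change of -0.55 and the histone methyltransferase SETD2 one of -0.47, while ASXL1 had one of 0.49. Of 17 genes of the microRNA machinery 11 lay below 0 (median -0.05, camera adjusted p = 0.67), with -0.43 for LIN28B and 0.34 for TNRC6B. At the locus of the microRNA cluster on chromosome 14, 3 of the 12 genes listed were measured. DLK1 averaged 15.9 ± 0.22 and 16.5 ± 0.11 (SD, n = 3), a log2 change of 0.63 with an adjusted p of 0.159 over all probe sets and 0.00656 over the list alone. RTL1 and DIO3 had log2 changes of -0.16 and -0.04, and the locus list, whose median of -0.04 and mean of 0.14 differ in sign, had a camera adjusted p of 0.67.

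Markers of blood lineages were next. The erythroid list had 21 of 32 measured members above 0 and a median log2 change of 0.10. KLF1, a master transcription factor of red cells, had a log2 change of 0.66 (SE 0.15), an adjusted p of 0.106 over all probe sets and 0.0317 over the list alone, and was the 1 member to pass over the list alone. The blood group genes KEL and XK had log2 changes of 0.65 and 0.49, and TAL1 had one of 0.41. The list did not pass camera (adjusted p = 0.12, and 0.763 with an estimated correlation) and passed fry (adjusted p = 0.00472). Of 23 megakaryocyte genes 13 lay above 0 (median 0.01, camera adjusted p = 0.565), with 0.87 for the tetraspanin CD9 and 0.72 for the integrin ITGA2B, neither of which was called (adjusted p = 0.159 and 0.235). Of 21 myelomonocytic genes 13 lay above 0 (median 0.07, adjusted p = 0.67), and ITGAM had a log2 change of 0.40. Of 19 lymphoid genes 12 lay at or below 0 (CD2 was unchanged, median -0.01) and camera pointed upward (adjusted p = 0.955). CD3D and PRF1, with log2 changes of 0.64 and -0.93, each had an adjusted p of 0.0323 over the list alone. The stem and progenitor list had 9 of 17 members below 0 (median -0.03, adjusted p = 0.796), with -0.47 for FLT3. The 17 epithelial and kidney line markers, kept as a check for cells of another type, had a median of 0.01, a camera test that pointed downward (adjusted p = 0.999) and 9 members above 0, with 0.30 for CLDN7 and -0.24 for EPCAM. JAK-STAT signalling had 17 of 27 members below 0 (median -0.06, adjusted p = 0.426), with -0.57 for STAT5A, -0.42 for STAT5B and 0.45 for the kinase JAK2.

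Metabolic lists had positive medians. Of 19 measured cholesterol synthesis genes 14 lay above 0 (median 0.15), including the squalene epoxidase SQLE at 0.45, MSMO1 at 0.49, HMGCS1 at 0.38 and LSS at 0.48. That list did not pass camera (adjusted p = 0.184, and 0.763 with an estimated correlation) and passed fry (adjusted p = 0.00246). Of 24 genes of oxidative phosphorylation 20 lay above 0 (median 0.09, camera adjusted p = 0.279), with 0.44 for NDUFA1 and 0.39 for COX5B. The list passed only without control replicate 3 (adjusted p = 0.0375, in a range of 0.0375 to 0.823 over its alternatives). Of 26 hypoxia and glycolysis genes 14 lay above 0 (median 0.02, adjusted p = 0.565), with 0.54 for the glucose transporter SLC2A1.

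Growth, stress and inflammatory lists did not pass camera either. Of 28 G2/M genes 18 lay below 0 (median -0.03, adjusted p = 0.28), with -0.50 for UBE2C and -0.46 for the kinase TTK. Of 24 G1/S genes 14 lay below 0 (median -0.02, adjusted p = 0.565), with -0.41 for the replication licensing factor CDC6. The 17 replication histone genes had a median of 0.03 (adjusted p = 0.796), and H4C1 had a log2 change of 0.34. Of 21 genes of ribosome biogenesis and MYC 14 lay below 0 (median -0.06, adjusted p = 0.308), with -0.40 for LYAR and -0.39 for NOP58. ER stress and heat shock genes lay at or below 0 for 15 of 21 members (HERPUD1 was unchanged, median -0.08, adjusted p = 0.426), with -0.34 for DNAJC3. The 28 ATF4 stress genes had a median of 0.005 and a mean of -0.01 (adjusted p = 0.955), with -0.74 for NUPR1 and 0.41 for FGF21. Immediate early genes lay at or below 0 for 13 of 23 members (FOS was unchanged, median -0.02, adjusted p = 0.67), with -0.62 for IER3 and -0.35 for ATF3. The 20 NF-kB genes had a median of 0.03 with a camera test that pointed downward (adjusted p = 0.955), and TNFAIP3 had a log2 change of 0.38. The 30 interferon genes had a median of 0.02 and a mean of -0.01 (adjusted p = 0.955), with -0.70 for IFIH1 and 0.45 for IFI6. Apoptosis genes lay above 0 for 15 of 26 members (median 0.01, adjusted p = 0.796), with -0.43 for BMF and -0.39 for BCL2.

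Over all 28 lists, 0 passed camera, 4 had an unadjusted p under 0.05, 0 passed with an estimated correlation and 2 passed the directional test of fry. The mixed test of fry asks whether members change in either direction and does not compare a list with other genes. It put 13 lists under 0.05. The lowest adjusted p-values were those of the reported targets and cholesterol synthesis (0.00163 each), then the erythroid, hypoxia and ATF4 lists (0.00318 each). The stromal list (0.00588), JAK-STAT (0.00608) and TGF-beta (0.015, the highest of the 13) also passed. The rate of this test for random lists was not examined. At an unadjusted limma p under 0.05 there were 2276 probe sets where 1072 would be expected by chance, so the test picks out no single theme. Of the 578 distinct genes measured on the lists, 3 were called over all probe sets (TWIST1, SPARC and TGFBR2), and all 3 fell.

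**Figure D4:**
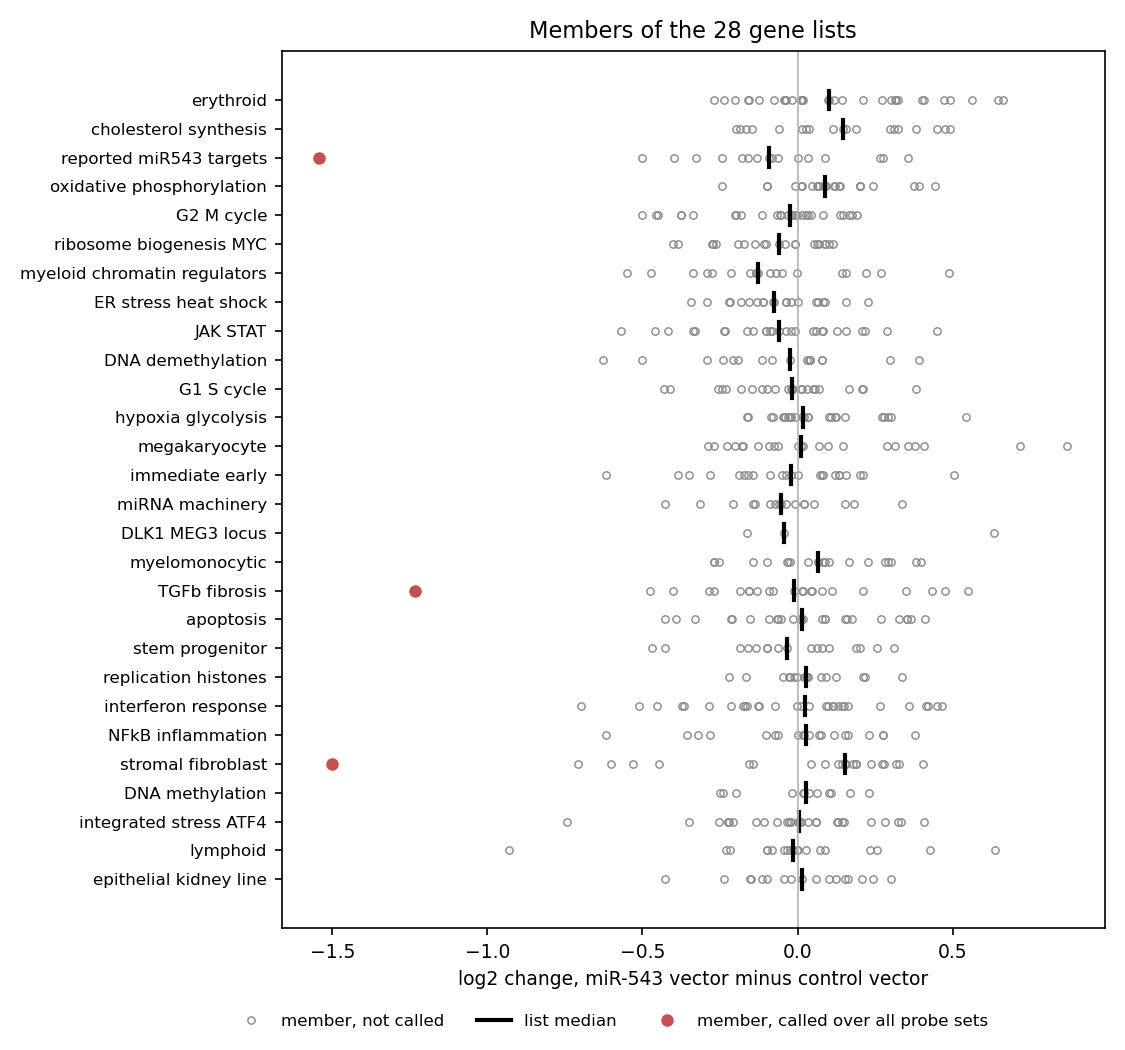
Log2 change (miR-543 vector minus control vector) of each measured member of the 28 gene lists, with open circles for members that were not called, red points for called members and black bars for the list median. The 3 called members, TWIST1 (-1.54), SPARC (-1.50) and TGFBR2 (-1.23), lie far from medians between -0.13 (myeloid chromatin regulators) and 0.15 (stromal and fibroblast genes).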

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

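All alternatives here were planned except the count on chromosome X, the gene families and the treat values of single genes, chosen after the data were seen, and where a count or call changed the cause was not tested unless fewer arrays or another threshold set it. The labels do not say whether equal replicate numbers mark paired samples. Deviations of arrays with the same replicate number correlated at 0.095, -0.053 and 0.018, and those with different numbers at -0.094 to 0.066. This check rests on 3 arrays per group and found no clear pairing, which does not exclude it. The fit with a replicate block gave 71 calls (12 rises, 59 falls), 61 of them shared with the 122, and 10 falls on chromosome X against 17. With that block TMEM54, TBXAS1, SLC7A8 and TGFBR2 were not called (adjusted p = 0.117, 0.0692, 0.0692 and 0.0682), nor was the CT47 family (0.0824). Trend and robust settings gave 252 calls (80 rises, 172 falls, 121 shared), the 50th-percentile filter 168 (51 rises, 99 shared), an unadjusted p under 0.05 with a 2-fold change 100 (16 rises, 76 shared), and treat 12 (0 rises, 12 falls, 12 shared, 10 of them named falls). A further quantile normalization gave 120 calls (118 shared), equal medians 120 (120 shared), the 30th-percentile filter 137, array weights 142 and 1 probe set per symbol 130. Leaving out 1 array, with fewer samples and so less power, gave 34 to 59 calls, 2 to 12 rises, 32 to 47 falls, 34 to 58 calls of at least 2-fold, 0 to 1 lists past the threshold and 5 to 13 falls on chromosome X. TET1 stayed between log2 changes of -0.61 and -0.45 and adjusted p-values of 0.108 and 0.499, and TET2 and TET3 did not pass in any of the 14 settings. Of 27 called genes named by rule, 13 (12 falls and CYTIP) were called in each of the 14 settings run for single genes (13 for IL1RAP), which leave out treat, and the direction of the 27 held in these. Of 1388 values of uncalled named genes, 10 passed: with trend and robust settings DLK1 (adjusted p = 0.00292), STAT5A (0.0145), CD9 (0.0273), SLC2A1 (0.0307), SUZ12 (0.0348), CD3D (0.0385), MSMO1 (0.0404), SQLE (0.0425) and NUPR1 (0.0455), and with the 50th-percentile filter KLF1 (0.0378). Without 1 array RTL1 ranged from -0.25 to 0.002 and DIO3 from -0.18 to 0.15. Other uncalled list members also moved without 1 array, for example FLT3 (-0.62 to -0.24), DNMT1 (-0.34 to -0.11), H4C1 (0.12 to 0.52), ITGAM (0.20 to 0.62) and CLDN7 (0.16 to 0.39). Of 279 list values 24 had the other direction, none of them past the threshold, and 3 passed: fry for cholesterol synthesis (0.00246) and erythroid genes (0.00472), 2 lists in all, and oxidative phosphorylation without control replicate 3 (0.0375). Direction turned under fry for the epithelial, interferon, ATF4 and NF-kB lists (0.901, 0.901, 0.985 and 0.985), with the 30th-percentile filter for the epithelial and NF-kB lists (0.846 and 0.846), and without 1 array at least once for DNA methylation (adjusted p = 0.721 to 0.975), epithelial (0.87 to 0.996), immediate early (0.295 to 0.975), ATF4 (0.626 to 0.975), lymphoid (0.67 to 0.975), NF-kB (0.612 to 0.996), replication histone (0.436 to 0.976), stromal (0.589 to 0.975) and TGF-beta lists (0.286 to 0.975). The variants of the seed match search that had been planned were not run, since transcript sequences were not used here. Signal over background was not tested, as no detection calls were used.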

Other observations

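The tests on chromosome X, on the gene families and on near-identical copies, and the count of splits for chromosome X, were chosen only after the result was seen. Some families of cancer-testis genes, which are normally read in germ cells and often in tumours, fell. Of 75 measured members of 13 families 12 fell, 0 rose and 60 lay below 0, with a median of -0.23, and camera over all members gave a p of 2.89e-17, or 0.00467 with an estimated correlation, on families defined after the falls were seen. Among members picked after their values were seen, PAGE5 fell (log2 change -1.45, SE 0.16, adjusted p = 0.00366), as did XAGE1B (-1.36), SSX1 (-1.23, SE 0.15, adjusted p = 0.00764) and MAGEA1 (-1.12, SE 0.14, adjusted p = 0.00795). Averaged by family, SSX fell (log2 change -1.12, SE 0.17, adjusted p = 4.98e-04, 6 of 8 members called), as did PAGE (-0.88, SE 0.14, adjusted p = 4.98e-04, 2 of 6) and VCX (-0.78, SE 0.14, adjusted p = 0.00101, 2 of 4), and these 3 families fell in 11 of 11 settings. CT47 fell by 0.56 (SE 0.18, adjusted p = 0.0381) with 0 of 5 members called, and did not pass without control replicates 1 or 2 (adjusted p = 0.138 and 0.0905) or miR-543 replicates 1 or 2 (0.112 and 0.169). CT47A3, CT47A6 and CT47A12 had identical values (log2 change -0.68 each), so the same profile was counted repeatedly in the CT47 mean. The other 9 families did not pass, with log2 changes of -0.33 for GAGE and XAGE, -0.28 for MAGEA, -0.25 for MAGEC, -0.19 for CT45, -0.10 for MAGEB, 0.01 for SPANX, 0.06 for CSAG and 0.29 for CTAG. Those of SPANX and CSAG changed sign in some settings, and GAGE and XAGE passed in 1 of 11 settings each. The control means of SPANX and MAGEB, 4.82 and 5.33, lay below the array medians of 5.99 to 6.01, where a fall is hard to see. In XAGE the called XAGE1B had a control mean of 12.1, while XAGE2, XAGE3 and XAGE5 lay at 3.66, 4.86 and 4.64. These family means therefore do not show that expressed members were unchanged.

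On chromosome X, 17 of 712 named probe sets fell where 3.5 would be expected, and 0 rose (Fisher's exact test, odds ratio 5.91, 95% interval 3.24 to 10.2, adjusted p = 1.38e-06 over 25 chromosome labels, with genes that are not independent). The 75 family members, all on chromosome X, held 12 of the 17. The count of 17 was 5 without control replicate 1, 13 without control replicate 2, 7 without control replicate 3, and 8, 9 and 7 without miR-543 replicates 1, 2 and 3. Outside the families 5 of 637 named probe sets on X fell, FGF13, the dystrophin gene DMD, ITM2A, ZNF711 and SYTL5 (odds ratio 1.91, 95% interval 0.6 to 4.7, Fisher's exact p = 0.197).

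The fall of the 12 cancer-testis genes was set against technical explanations. Loss of X segments in the miR-543 cells would lower neighbouring genes too, but the 92 expressed neighbours outside the families had a median of 0.028 (95% interval -0.013 to 0.060), with 0 called falls, against a median of -1.19 for the 12 fallen members. These neighbours were pooled over all loci of the fallen members and held only named genes. Some unnamed probe sets whose identifiers place them on X were themselves called as falls, for example TC0X00007285.hg.1 (-1.05). A loss confined to 1 locus or within a gene cluster is therefore not excluded. Near-identical copies read by the same probes stay open as a source of part of the count: 4 families fell when each was 1 averaged value, but the families were chosen on their falls. Values identical to another were found for 5 members, but for 0 called probe sets, so exact duplicates added nothing to the 12 falls. A shift of bright probe sets by the normalization would lower other genes of the same brightness. The 10000 lists of other genes matched on mean signal had a typical median of 0.00 and a lowest of -0.11, against -0.23 for the 75 members (percentile 0, which by itself restates that the families were chosen on their falls). The arrays had already been normalized to near-equal medians and quartiles, which holds such lists near 0, so this comparison cannot decide. With 10 splits of the 6 arrays no share under 0.05 is possible: the real one had 17 X falls, matched by 1 split, itself, and the highest other had 0. Every other split called 0 probe sets in all, so its X count could only be 0 and is no separate test of chromosome X. Whether the miR-543 vector or drift between the cultures lies behind the falls was not tested.

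Falls outnumbered rises, 94 to 28. A shift of each array to the same median, meant to remove a uniform offset between the arrays, moved no array by more than 0.0108, so the 78.3% of falls among the calls after it, beside 77% before, decides nothing. The count of 122 calls belonged to 1 split of 10, the real one, and the highest other gave 0, while for lists past the threshold the real split gave 0, the highest other 3, and 10 of 10 splits gave at least as many. With 10 splits a share under 0.05 is not possible. The other splits mix the 2 groups, so a difference between the vectors adds to their spread and lowers their count of calls. No biological explanation of the surplus was tested.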
